A study of Mus musculus with 12 samples.

How the data were processed

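The series holds 12 arrays of RNA from sorted cells of mouse embryos (strain CD-1) at embryonic day 7.5. Per the labels, each sample held 3000 sorted cells, its messenger RNA was turned into cDNA and amplified by a global PCR method (SuperAmp), and 250 ng of cDNA was labelled with the dye Cy3. Each sample was hybridised to its own 1-colour Agilent whole-genome array. Per the file headers, the scanned arrays were read with Agilent Feature Extraction version 10.5.1.1 and the probe positions refer to mouse genome build mm8. The values of the processed signal are intensity per spot, per the file headers: background was subtracted and spatial trends were removed within each array, spots not above background hold a substitute value, and no scaling between arrays had been applied. The deposited files also hold flags of 0 or 1 per spot (well above background, saturated, outlier), which is the other kind of value used here. The authors' table of all samples gives intensity divided by the median of the array, not on a log scale: in every column the median is 1, and the ratio of the processed signal to the table's value is the array's median signal. The design text names GeneSpring GX as the authors' analysis software; its settings are not given in the sources used here.

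All values were recomputed from the scanner files. The 1639 control spots of each array were left out, which leaves 43379 spots and 41174 probes. Spots marked as outliers were set aside, the log2 of the processed signal was taken, the 75th percentile of the array (also on the log2 scale) was subtracted, and spots of 1 probe were averaged. Probe names were brought up to date with a RefSeq gene table (GRCm38.p6, used for names only): 24375 probes were named by accession, 4647 through a gene name shared with such a probe, 2619 by symbol, 1514 by synonym, and 8019 kept the name in the file. This gave 27548 gene names, each represented by the probe with the highest mean over the 12 arrays. Genes well above background on all 3 arrays of at least 1 group were tested, 22720 in all, of which 17447 were well above background on all 12 arrays. In these, 171 values in 161 genes were missing after the outlier flags. No spot was saturated.

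One linear model with the 4 fractions as groups was fitted to the 12 arrays with limma (version 3.58.1, in R 4.3.3, with the package data.table, version 1.17.8), with moderated tests and Benjamini-Hochberg adjustment over all genes of a comparison. A gene counts as changed at an adjusted p under 0.05. There were 5 comparisons between fractions and the interaction, the difference between the effect of Endoglin among Flk1 positive and among Flk1 negative cells. The effect of Endoglin here means the difference between fractions sorted with and without the protein, which was itself not altered. Errors of log2 folds are standard errors from the model and errors of group levels are SD of 3 arrays. The model takes 1 spread per gene for all 4 fractions. The median SD of genes was 1.01 in Eng-Flk1-, 0.577 in Eng-Flk1+, 0.667 in Eng+Flk1+ and 0.563 in Eng+Flk1-. The SE may thus be too small in comparisons with Eng-Flk1- and too large in the others. For a gene well above background on no array of the lower group and on all 3 arrays of the higher, the fold is given as a lower bound ("at least N-fold"): the mean log2 level of the higher group minus that of the lower group, after each array's values in the lower group were raised to the lowest level of any probe well above background on that array where they lay under it. This floor is that of the dimmest such probe, so the bound is a convention and not a guaranteed limit. Folds of genes not well above background on only some arrays of the lower group are given as measured and depend in part on values near background. Exact tests of 3 against 3 arrays cannot give a two-sided p under 0.1, so they were used only for the 2 sorting markers over 6 against 6 arrays.

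Named genes were picked by a rule fixed before the data were examined, as were the gene lists, the comparisons and most of the alternative settings. The rule takes Eng and Kdr, the genes of the sorting markers. It takes the 8 largest rises and 8 largest falls among changed genes whose 2 groups of arrays do not overlap and that are well above background on all 6 arrays. It takes the 4 highest lower bounds each way among changed, non-overlapping genes well above background on all 3 arrays of 1 of the 2 groups and on none of the other. It also takes up to 4 members of each gene list with the lowest p. Among these largest changes and bounds, names that are only clone, accession or probe identifiers were passed over. A gene named outside the rule is said to be so, and 1 result that the rule takes is not reported here. Old gene names that the table could not update stand as in the file.

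The 24 gene lists are primitive erythroid, blood and hemangioblast regulators, endothelial, cardiac mesoderm, primitive streak and nascent mesoderm, paraxial mesoderm, extraembryonic mesoderm and allantois, epiblast and pluripotency, neuroectoderm, definitive endoderm and axial mesoderm, visceral endoderm, trophoblast and extraembryonic ectoderm, maternal decidua, macrophage and leukocyte, primordial germ cell, epithelial, mesenchymal, BMP and TGF-beta response, Notch response, Wnt response, heme synthesis and iron uptake, hypoxia and glycolysis, cell cycle, and dissociation stress. Some genes belong to more than 1 list. Each list was tested against all other genes with camera from limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 24 lists, and again with the correlation estimated from the data. Members are also counted after adjustment over all genes and when adjusted over the list alone.

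The arrays were hybridised on 3 slides that nearly follow the fractions: slide 1 holds the 3 Eng-Flk1- arrays and Eng-Flk1+ replicate 1, slide 2 holds Eng-Flk1+ replicates 2 and 3 and Eng+Flk1+ replicates 1 and 2, and slide 3 holds Eng+Flk1+ replicate 3 and the 3 Eng+Flk1- arrays. A model with the slide as a block compares fractions within slides where a slide holds both and otherwise through a chain of slides. For the 3 comparisons whose fractions share a slide, a model of group means per slide gives nearly the same estimates as the block, apart where values are missing. On slides 1 and 3 the second fraction has 1 array, so the block estimates of Eng-Flk1+ against Eng-Flk1- and of Eng+Flk1+ against Eng+Flk1- rest on that 1 array. The block estimate of the interaction combines these 2 and rests on both arrays, Eng-Flk1+ replicate 1 and Eng+Flk1+ replicate 3. The chain from Eng-Flk1- to Eng+Flk1- also passes through both, and that to Eng+Flk1+ through Eng-Flk1+ replicate 1.

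The alternatives planned before the data were examined were normexp background correction with an offset of 50, quantile normalization, centring each array on its median, the authors' table, no filter on dim probes, a filter asking for signal well above background on all 12 arrays, an intensity trend in the moderated variances, the slide as a block, comparison within slides, the replicate number as a block, a fit of the compared arrays alone, every probe tested on its own, an adjusted p under 0.01, a minimum fold of 2, an estimated correlation in camera, and leaving out each array in turn. The array quality weights of limma, and fits without the 3 Eng-Flk1- arrays, were chosen after seeing the data. Splits of the arrays into other groups of the same sizes were also run. The pipeline was tested on simulated data. In arrays simulated from the mean and spread of each gene, with 50 genes changed by each known factor, 0 of those changed 2-fold were recovered in each of 5 comparisons, and between 28% and 50% of those changed 16-fold were. In the 3 comparisons against Eng-Flk1-, 7 of 53, 4 of 42 and 4 of 45 simulated calls were false, and in the other 2 there were 0 false calls. The simulation gave all 4 fractions the same spread per gene, so the false calls differ between comparisons by the draw alone. It did not hold the wider spread of the Eng-Flk1- arrays, so these rates may not carry over to the real comparisons. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.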

Results

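Gene expression was measured in cells of mouse embryos at embryonic day 7.5, the stage at which the first blood and vessel precursors arise from mesoderm. Cells of a pool of about 300 embryos from 25 litters were stained for 2 surface proteins and sorted into 4 fractions. Endoglin (gene Eng) is a co-receptor for ligands of the TGF-beta family, found on endothelial cells. Flk1 (gene Kdr) is a receptor for vascular endothelial growth factor and marks precursors of blood and vessels. The fractions lack both proteins (Eng-Flk1-), carry Flk1 alone (Eng-Flk1+), carry both (Eng+Flk1+) or carry Endoglin alone (Eng+Flk1-), each with 3 arrays (n = 3). All come from 1 pool, so the p-values measure the spread between sorted samples of that pool, which may be technical, and not the spread between embryos. The share of spots well above background was 73.8%, 76.3% and 66.6% on the 3 Eng-Flk1- arrays (mean 72.2 ± 5.06, SD). It was 82.7% ± 0.697 in Eng-Flk1+, 81.9% ± 1.56 in Eng+Flk1+ and 81.4% ± 1.46 in Eng+Flk1-. The Eng-Flk1- arrays also differed more among themselves: across genes, the correlation between pairs of them was 0.675 to 0.720, against 0.813 to 0.911 for pairs within the other fractions (genes are not independent replicates). Levels are log2 signals relative to the 75th percentile of the array, and folds are differences of these levels with their SE.

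The transcripts of the sorting markers were compared first. Kdr (probe at 76214981 to 76215040 on chromosome 5, build mm8) had a mean level of 1.11 ± 0.76 (SD, n = 3) in Eng-Flk1+ and 1.63 ± 0.18 in Eng+Flk1+, against -6.20 ± 1.56 in Eng-Flk1- and -5.38 ± 1.87 in Eng+Flk1-. The Flk1 positive fractions were higher by 7.16 over 6 against 6 arrays (exact permutation test, two-sided, p = 0.00216, 924 splits). Kdr was well above background on 1 of the 3 Eng-Flk1- arrays and on 2 of the 3 Eng+Flk1- arrays, so the size of its folds rests in part on values near background. Eng (probe at 32503799 to 32503858 on chromosome 2) had a mean level of -0.49 ± 0.86 in Eng-Flk1-, 0.49 ± 1.02 in Eng-Flk1+, 2.09 ± 0.93 in Eng+Flk1+ and 0.48 ± 0.55 in Eng+Flk1-. The Endoglin positive fractions were higher by 1.29, which missed the threshold (exact permutation test, two-sided, p = 0.0649, 924 splits). Eng did not pass in any comparison of single fractions. Its highest fold was 2.59 ± 0.69 in Eng+Flk1+ against Eng-Flk1- (limma adjusted p = 0.0936).

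**Figure D1:**
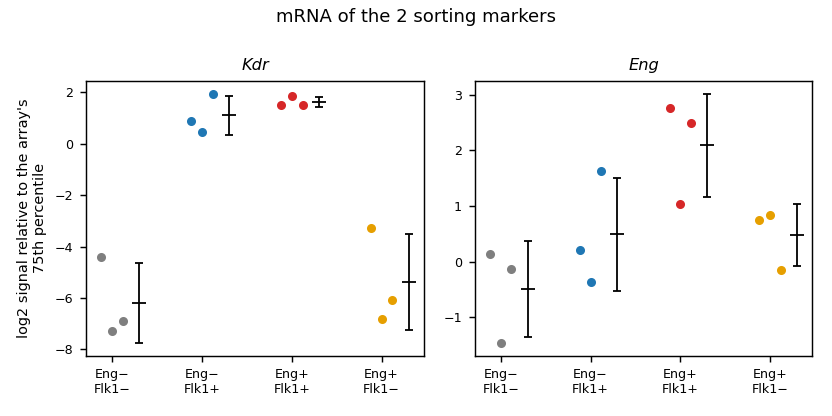
Levels of Kdr and Eng on each of the 12 arrays (y axis: log2 signal relative to the 75th percentile of the array) by fraction (x axis); points are arrays, and bars are the mean ± SD of 3. Kdr lies at 1.11 and 1.63 on average in the Flk1 positive fractions and at -6.20 and -5.38 in the others, while the fractions overlap for Eng.

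Among Flk1 positive cells, Eng+Flk1+ against Eng-Flk1+ asks what sets cells with Endoglin apart. Genes of blood vessel lining were higher as a group in Eng+Flk1+. Of the 20 endothelial genes, 18 had positive folds and the list rose by a median log2 of 1.62 (camera adjusted p = 3.30e-10). The lowest p values in the list were those of Erg, an endothelial transcription factor (2.60 ± 0.55, limma adjusted p = 0.248), the adhesion molecule Pecam1 (3.48 ± 0.76, 0.276), the receptor Tie1 (4.74 ± 1.08, 0.314) and Icam2 (2.94 ± 0.74, 0.397). Over all genes 0 of the 20 passed, and 9 rose when adjusted over the list alone.

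Of 22720 genes, 6 changed in Eng+Flk1+ against Eng-Flk1+, 2 higher and 4 lower. Tceal1 fell (-4.25 ± 0.45, limma adjusted p = 0.0147), and Ttc21b, a protein of transport within cilia, was at least 66.0-fold lower (0.0478). Fbxo17, named after its values were seen, had a fold of -4.89 ± 0.61 (0.0478), and the other 3 are known by accessions alone. Kdr had a fold of 0.52 ± 0.96 and Eng of 1.61 ± 0.69 (both 0.999). Cer1, a secreted inhibitor made by anterior endoderm, was at least 33.1-fold lower and the epithelial surface protein Cd24a had a fold of -2.55 ± 0.44, which did not pass (both 0.131).

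A further 5 lists were called between the Flk1 positive fractions with the preset correlation alone. The 18 blood and hemangioblast regulators had a median of 0.56 (camera adjusted p = 0.00748; adjusted p = 0.205 with an estimated correlation), with 0 members passing either way. Among the members, Spi1 had a fold of 3.24 ± 1.05, and Etv2, which starts the blood and vessel programme, one of -1.55 ± 0.51 (limma adjusted p = 0.740 and 0.756). Allantois and extraembryonic mesoderm genes had a median of -0.85 (0.00345; adjusted p = 0.0545 with an estimated correlation), and 2 of 14 fell when adjusted over the list alone. Epithelial and mesenchymal genes had medians of -0.10 and -0.29 (both 0.00697; adjusted p = 0.0545 with an estimated correlation for both), with 2 of 17 and 0 of 15 falling when adjusted over the list alone. The 16 cell cycle genes had a median of -0.54 (0.00697; adjusted p = 0.192 with an estimated correlation), with 0 falling.

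With the slide as a block, limma called 0 genes in Eng+Flk1+ against Eng-Flk1+ (774 at an unadjusted p under 0.05, against 1085 without the block), and the slide holding both groups gave the same. The endothelial list kept a median of 1.58 (camera adjusted p = 1.88e-06; 3.35e-16 to 0.0349 over its 24 alternatives), while the other 5 lists lost their calls (medians 0.82 and -0.69 for blood regulators and allantois, both 0.0538; -0.21 and -0.39 for epithelial and mesenchymal, both 0.0906; -0.44 for cell cycle, 0.110). Over the 24 alternatives their adjusted p lay between 0.00496 and 0.205, 0.000126 and 0.127, 0.00576 and 0.0906, 0.00148 and 0.109, and 0.00108 and 0.194. Leaving out 1 array ended the call of blood regulators (Eng-Flk1+ replicate 2 and Eng+Flk1+ replicate 1, 0.0533 and 0.122), of mesenchymal genes (Eng-Flk1+ replicate 1, 0.109) and of cell cycle genes (Eng-Flk1+ replicate 1 and Eng+Flk1+ replicate 2, 0.146 and 0.194). Normexp called 3 genes, all higher and none of the 6, an intensity trend called 0 (1049 at an unadjusted p under 0.05), and array quality weights, chosen after seeing the data, called 51 (25 higher, 26 lower). The count of genes was 3 without Eng+Flk1- replicate 3, 22 without Eng+Flk1+ replicate 3 and 13 without the 3 Eng-Flk1- arrays, a fit chosen after seeing the data. In that last fit Pecam1 rose (3.48 ± 0.35, limma adjusted p = 0.0161; 0.0161 to 0.99995 over its 26 alternatives).

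Among Flk1 negative cells, Eng+Flk1- against Eng-Flk1- asks the same of Endoglin in the absence of Flk1. Genes of trophoblast and extraembryonic ectoderm, and of allantois, were higher in Eng+Flk1-, and genes of visceral endoderm were lower. Of 14 trophoblast genes 3 rose and 0 fell over all genes (7 rose when adjusted over the list alone), with a list median of 1.51 (camera adjusted p = 4.91e-06). They were Elf5, a trophoblast stem cell factor (3.38 ± 0.47, limma adjusted p = 0.00798), Esrrb (5.53 ± 0.95, 0.0208) and Rhox9 (2.61 ± 0.48, 0.0276). Of 14 genes of extraembryonic mesoderm and allantois 2 rose (5 rose and 1 fell when adjusted over the list alone), with a median of 1.74 (camera adjusted p = 0.00157). They were Bmp4 (6.20 ± 0.62, limma adjusted p = 0.00150), a growth factor of the extraembryonic region, and the transcription factor Foxf1 (5.04 ± 0.75, 0.00999).

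Of 17 visceral endoderm genes 6 fell in Eng+Flk1- against Eng-Flk1- and 0 rose (7 fell and 1 rose when adjusted over the list alone), with a median of -2.50 (camera adjusted p = 7.52e-07). Among them were the lipid carriers Apoa4 (-4.86 ± 0.75, limma adjusted p = 0.0128) and Apoc2 (-4.20 ± 0.69, 0.0167), the thyroid hormone carrier Ttr (-3.26 ± 0.52, 0.0141) and the uptake receptor Cubn (-5.11 ± 1.08, 0.0495). Of 9 genes of definitive endoderm and axial mesoderm 1 fell, Cer1, at least 232-fold lower (0.00434); 2 fell when adjusted over the list alone, and the median was -1.09 (camera adjusted p = 0.00260). Of 11 neuroectoderm genes 1 fell, the head patterning factor Otx2, at least 162-fold lower (limma adjusted p = 0.0339); 3 fell when adjusted over the list alone, and the median was -0.61 (camera adjusted p = 0.0379; adjusted p = 0.279 with an estimated correlation). The adult alpha globin genes Hba-a1 (-7.55 ± 1.104, limma adjusted p = 0.00938) and Hba-a2 (-6.48 ± 0.79, 0.00418) also fell.

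In all, 331 genes changed in Eng+Flk1- against Eng-Flk1-, 280 higher and 51 lower. The largest rises included Anxa5 (6.63 ± 0.72, limma adjusted p = 0.00255), Otub1 (6.33), S100a6 (5.93), Dad1, a subunit of the enzyme that attaches sugars to new proteins (5.92 ± 0.40, 0.000259), Mrpl30 (5.87) and the respiratory chain subunit Ndufv2 (5.78). Among genes well above background on all Eng+Flk1- arrays and on no Eng-Flk1- array, Mkks was at least 121-fold, Ddb2 at least 110-fold, Txndc12 at least 76.4-fold and Tspan14 at least 66.3-fold higher. The cardiac mesoderm factor Tbx20 rose by 4.08 ± 0.72 (0.0230) and Cd24a fell by 2.56 ± 0.44 (0.0210). Npl (-6.68), Rnf32 (-5.80), Crmp1 (-5.39) and Clic6 (-5.03) were among the largest falls.

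The 2 groups of Eng+Flk1- against Eng-Flk1- share no slide, so slide and fraction are told apart only through the chain of slides. The block left 0 genes called by limma (1007 at an unadjusted p under 0.05, against 3266). The trophoblast and allantois lists kept medians of 1.21 and 1.81 (camera adjusted p = 0.00171 and 0.0182; 7.34e-08 to 0.0120 and 0.000452 to 0.0477 over their 22 alternatives). The visceral endoderm, definitive endoderm and neuroectoderm lists lost their calls (medians -1.36, 0.09 and -0.16; 0.0695, 0.263 and 0.956). Over their alternatives these lists lay between 8.84e-08 and 0.0695, 0.00126 and 0.382, and 0.0117 and 0.956. The count of genes was 513 without Eng-Flk1- replicate 1, 851 without Eng-Flk1- replicate 2, 208 without Eng-Flk1+ replicate 3, and 150, 162 and 149 without Eng+Flk1- replicates 1, 2 and 3. Without Eng-Flk1- replicate 2 or 3, or Eng+Flk1- replicate 1 or 2, or Eng+Flk1+ replicate 2, the neuroectoderm call was lost (0.102, 0.0999, 0.101, 0.0507 and 0.0544).

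**Figure D2:**
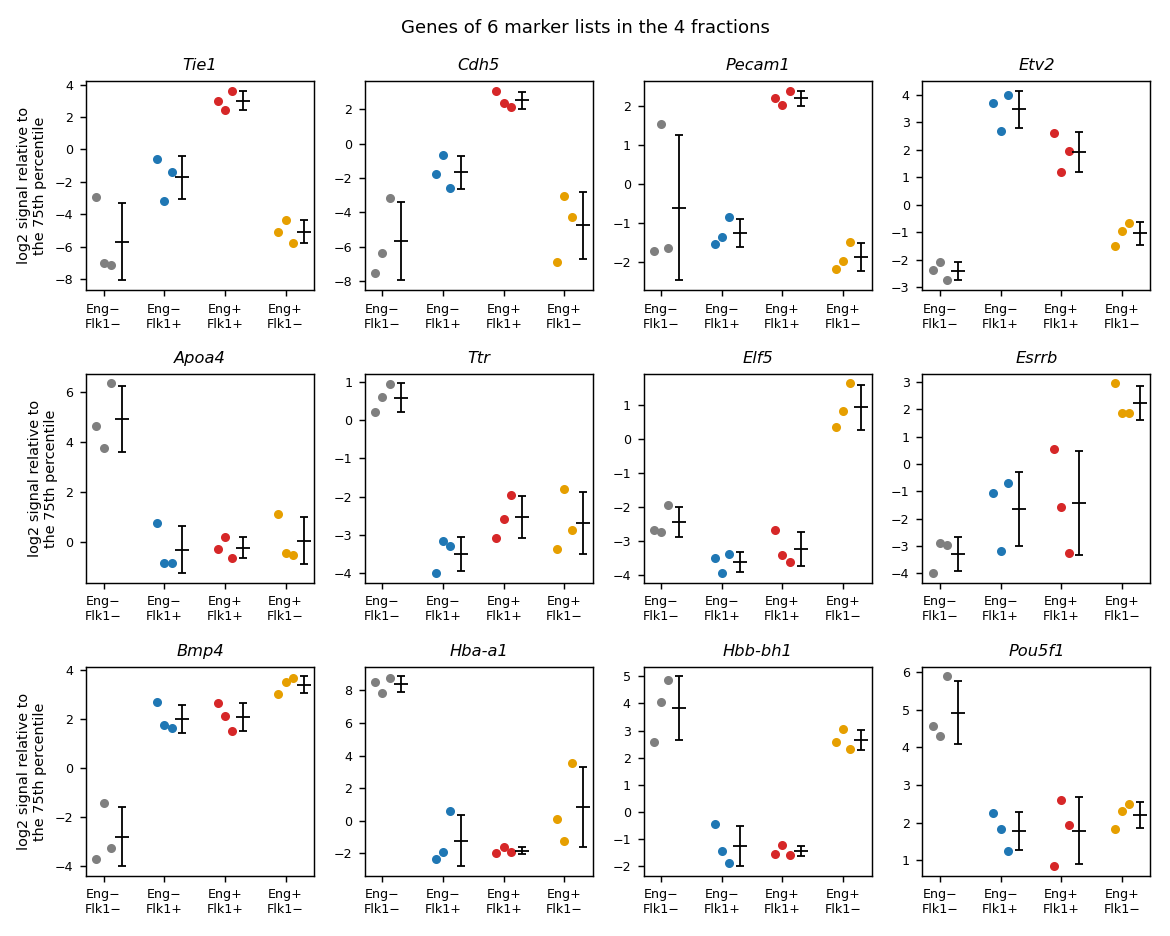
Levels of 12 genes on each array (y axes: log2 signal relative to the 75th percentile of the array) by fraction (x axes); points are arrays and bars are the mean ± SD of 3. Tie1 and Cdh5 are highest in Eng+Flk1+, Elf5 and Esrrb in Eng+Flk1-, and Hba-a1 in Eng-Flk1-, where its mean is 8.38.

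Among Endoglin negative cells, Eng-Flk1+ against Eng-Flk1- asks what Flk1 marks. Vessel lining genes and mesenchymal genes were higher in Eng-Flk1+, and genes of visceral endoderm, epiblast, epithelium and primitive red cells were lower. Kdr rose by 7.31 ± 0.96 (limma adjusted p = 0.00526). Of 18 blood and hemangioblast regulators 3 rose and 0 fell (4 rose when adjusted over the list alone), with a median of 1.04 (camera adjusted p = 0.00105; adjusted p = 0.0860 with an estimated correlation). They were Etv2 (5.88 ± 0.51, limma adjusted p = 0.000498), Hhex (4.34 ± 0.63, 0.00791) and Tal1, a master regulator of blood (3.78 ± 0.71, 0.0254). Of 20 endothelial genes 3 rose (9 when adjusted over the list alone), with a median of 1.98 (camera adjusted p = 2.30e-05). They were Sox18 (4.205 ± 0.56, limma adjusted p = 0.00549), Egfl7 (3.84 ± 0.65, 0.0167) and Plvap (3.05 ± 0.62, 0.0335). Of 15 mesenchymal genes Twist1 alone passed over all genes (at least 37.4-fold higher, 0.00354) and 6 rose when adjusted over the list alone (median 0.95, camera adjusted p = 0.00101).

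Of 14 genes of extraembryonic mesoderm and allantois, Twist1, Bmp4 (4.82 ± 0.62, limma adjusted p = 0.00482) and Foxf1 (5.43 ± 0.75, 0.00627) rose in Eng-Flk1+ against Eng-Flk1-. When adjusted over the list alone 5 rose and 1 fell, and the median was 1.11 (camera adjusted p = 0.0113; adjusted p = 0.0815 with an estimated correlation). Of 11 Notch response genes 0 passed either way (median 0.98, camera adjusted p = 0.0355; adjusted p = 0.0860 with an estimated correlation). The heart and vessel factor Mef2c (5.13 ± 0.67, limma adjusted p = 0.00502) and the endothelial receptor Acvrl1 (4.99 ± 0.95, 0.0267), which acts with Endoglin, also rose.

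Of 17 visceral endoderm genes all had negative folds in Eng-Flk1+ against Eng-Flk1- and 5 fell (6 when adjusted over the list alone), with a median of -2.54 (camera adjusted p = 3.52e-08). Apoa1 (-6.13 ± 0.92, limma adjusted p = 0.00907), Apoa4 (-5.23 ± 0.75, 0.00772), Apoc2 (-4.42 ± 0.69, 0.0105) and Ttr (-4.07 ± 0.52, 0.00439) were among them. Of 10 epiblast and pluripotency genes 1 fell, Pou5f1 (-3.14 ± 0.58, 0.0234), and 4 fell when adjusted over the list alone (median -1.41, camera adjusted p = 0.00134). Of 17 epithelial genes 1 fell, the protease Prss8 (-4.91 ± 0.91, limma adjusted p = 0.0237), and 3 fell when adjusted over the list alone (median -1.19, camera adjusted p = 0.00200). Of 17 primitive erythroid genes 2 fell over all genes and over the list alone, with a median of -0.97 (camera adjusted p = 0.00783): the embryonic globin Hbb-bh1 (-5.08 ± 0.60, limma adjusted p = 0.00353) and the adult globin Hba-a1 (-9.60 ± 1.104, 0.00290). Hba-a2 (-7.68 ± 0.79, 0.00150) and Eraf, a chaperone of alpha globin (-5.24 ± 0.78, 0.00838), also fell. The 9 definitive endoderm genes (median -1.57, camera adjusted p = 0.00887; adjusted p = 0.0511 with an estimated correlation) and 11 neuroectoderm genes (median -0.77, camera adjusted p = 0.0146; adjusted p = 0.184 with an estimated correlation) had 0 members passing over all genes, and 0 and 3 fell when adjusted over the list alone.

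In all, 435 genes changed in Eng-Flk1+ against Eng-Flk1-, 373 higher and 62 lower. Among genes well above background on all 6 arrays, the largest rises outside the lists included Dad1 (6.76 ± 0.40, limma adjusted p = 4.51e-05), Otub1 (6.17), Psmg1 (5.87), Tspan7 (5.87), the mitochondrial DNA polymerase Polg (5.79 ± 0.40, 0.000176), Mrpl30 (5.53) and Btbd1 (5.47). Tspan14 was at least 138-fold, Txndc12 at least 121-fold, Mkks at least 83.2-fold and the thrombin receptor F2r at least 81.4-fold higher. Sp8 (-7.76), Rnf32 (-6.41) and St14 (-6.09) fell, and Cldn23, a tight junction protein, was at least 15.8-fold lower.

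Only slide 1 holds both groups, with 1 Eng-Flk1+ array, on which the block estimates rest. With the slide as a block limma called 16 of the 435 genes (2082 at an unadjusted p under 0.05, against 4021), all higher, including Dad1 (6.89 ± 0.64), Polg (6.16), Txndc12, Mkks and F2r. Kdr kept a fold of 7.10 ± 1.52 but not its call (0.193; 0.00251 to 0.193 over its alternatives). Of the 11 lists called in Eng-Flk1+ against Eng-Flk1-, 9 kept their calls with the block, with medians of 1.00 (blood regulators), 2.21 (endothelial), 1.58 (allantois), 0.91 (mesenchymal), -2.46 (visceral endoderm), -1.07 (epiblast), -1.61 (epithelial), -1.03 (primitive erythroid) and -1.21 (definitive endoderm). Cell cycle gained a call with the block (median 0.83, against 0.52 without it). Neuroectoderm (-0.95, 0.0851; 0.00785 to 0.245 over its alternatives) and Notch response (0.68, 0.0924; 0.0180 to 0.107) lost theirs. The count of genes was 1011 without Eng-Flk1- replicate 2 and 175, 255 and 164 without Eng-Flk1+ replicates 1, 2 and 3. The call of the allantois list was lost without Eng-Flk1- replicate 2 (0.0588), that of neuroectoderm without Eng-Flk1- replicate 3 (0.122), and that of Notch response without Eng-Flk1- replicate 1 or 2 or Eng-Flk1+ replicate 2 (0.0540, 0.107 and 0.0831).

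Among Endoglin positive cells, Eng+Flk1+ against Eng+Flk1- asks what Flk1 marks there. Vessel lining genes were higher in Eng+Flk1+, and epithelial and trophoblast genes were lower. Of 20 endothelial genes 6 rose and 0 fell over all genes (14 rose when adjusted over the list alone), with a median of 3.13 (camera adjusted p = 6.48e-26). Among them were the angiopoietin receptor Tek (8.64 ± 1.30, limma adjusted p = 0.0253), its partner Tie1 (8.09 ± 1.08, 0.0155), Sox18 (7.68 ± 0.56, 0.000587) and Egfl7 (4.61 ± 0.65, 0.0190). Kdr rose by 7.01 ± 0.96 (0.0168). Of 11 Notch response genes the receptor Notch1 rose (3.36 ± 0.48, 0.0202), over all genes and when adjusted over the list alone, and the list's median was 1.12 (camera adjusted p = 0.00309). Of 18 blood and hemangioblast regulators 0 passed over all genes and 8 rose when adjusted over the list alone (median 1.69, camera adjusted p = 2.18e-12); Etv2 had a fold of 2.96 ± 0.51 (limma adjusted p = 0.0501).

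All 17 epithelial genes had negative folds in Eng+Flk1+ against Eng+Flk1-: 2 fell over all genes and 11 when adjusted over the list alone, with a median of -3.11 (camera adjusted p = 9.77e-18). They were the adhesion protein Cdh1 (-3.71 ± 0.63, limma adjusted p = 0.0477) and the protease inhibitor Spint2 (-6.43 ± 1.09, 0.0484). Of 14 trophoblast genes 1 fell, Elf5 (-4.16 ± 0.47, 0.00749), and 8 fell when adjusted over the list alone (median -1.86, camera adjusted p = 1.09e-10). Of 14 genes of extraembryonic mesoderm and allantois 0 passed over all genes and 2 fell when adjusted over the list alone (median -1.005, 0.000370). Of 17 primitive erythroid genes Hbb-bh1 fell (-4.10 ± 0.60, limma adjusted p = 0.0232); 1 rose and 1 fell when adjusted over the list alone (median -0.58, camera adjusted p = 0.00590). Of 10 epiblast genes 0 passed over all genes and 2 fell when adjusted over the list alone (median -0.69, camera adjusted p = 0.00499; adjusted p = 0.0592 with an estimated correlation). The 14 hypoxia and glycolysis genes had a median of -0.42 with 0 passing either way (camera adjusted p = 0.0117; adjusted p = 0.248 with an estimated correlation).

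In all, 61 genes changed in Eng+Flk1+ against Eng+Flk1-, 35 higher and 26 lower. Among genes well above background on all 6 arrays, the largest rises outside the endothelial list were those of Rhoj, a small GTPase of vessels (6.57 ± 0.48, limma adjusted p = 0.000587), Arap3 (5.84 ± 0.52, 0.00190), Tmem204 (5.64), Rassf2 (5.53), Cnrip1 (5.49), Mef2c (5.24) and Zfp711 (4.78). Id2, an inhibitor of transcription factors (-6.89 ± 1.05, 0.0278), the metal binding protein Mt2 (-6.15 ± 0.55, 0.00190), Dnmt3l (-4.52), Sdc4 (-4.47), Rnf128 (-4.27) and Klhl13 (-4.04) fell. Bmp8b was at least 22.3-fold and Cdkn2a at least 9.79-fold lower, and Itpripl2 was at least 4.51-fold and Aspn at least 3.27-fold higher.

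Only slide 3 holds both groups of Eng+Flk1+ against Eng+Flk1-, with 1 Eng+Flk1+ array, on which the block estimates rest. Limma called 12 genes with the slide as a block (1184 at an unadjusted p under 0.05, against 1498), of which 7 were among the 61, including Sox18 (8.03 ± 0.79), Rhoj (7.24), Id2 (-9.46) and Mt2 (-6.87). Kdr kept a fold of 6.91 ± 1.52 but not its call (0.293; 0.000785 to 0.297 over its alternatives). Of the 9 lists called in Eng+Flk1+ against Eng+Flk1-, 7 kept their calls with the block, with medians of 3.68 (endothelial), 1.45 (blood regulators), 1.74 (Notch response), -3.67 (epithelial), -1.93 (trophoblast), -1.26 (allantois) and -0.98 (primitive erythroid). Visceral endoderm gained a call with the block (median -0.86, against -0.40 without it). Epiblast (-0.46, 0.321; 0.00160 to 0.321 over its alternatives) and hypoxia (-0.40, 0.443; 0.00444 to 0.443) lost theirs. The count of genes was 106 without Eng-Flk1- replicate 3, 36 without Eng+Flk1+ replicate 1, 31 and 28 without Eng+Flk1- replicates 2 and 3, and 129 without the 3 Eng-Flk1- arrays, a fit chosen after seeing the data. The hypoxia call was lost without Eng+Flk1+ replicate 2 (0.131) and without Eng+Flk1- replicate 2 (0.0559).

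The double positive fraction against the double negative one, Eng+Flk1+ against Eng-Flk1-, compares cells carrying both proteins with cells carrying neither. Vessel lining genes and blood regulators were higher in Eng+Flk1+, and genes of visceral endoderm, epithelium and epiblast were lower. Of 20 endothelial genes 10 rose and 0 fell (15 rose when adjusted over the list alone), with a median of 3.01 (camera adjusted p = 3.04e-14). Among them were Tie1 (8.70 ± 1.08, limma adjusted p = 0.00263), the endothelial cadherin Cdh5 (8.22 ± 1.18, 0.00565), Sox18 (6.31 ± 0.56, 0.000429) and Egfl7 (4.80 ± 0.65, 0.00426). Of 18 blood and hemangioblast regulators 6 rose (9 when adjusted over the list alone), with a median of 2.12 (camera adjusted p = 4.11e-08). Etv2 (4.33 ± 0.51, limma adjusted p = 0.00214), Hhex (4.17 ± 0.63, 0.00755), Tal1 (3.97 ± 0.71, 0.0180) and Fli1 (3.65 ± 0.65, 0.0213) were among them. Kdr rose by 7.83 ± 0.96 (0.00263). Of 11 Notch response genes 1 rose, Hey1 (5.13 ± 1.16, 0.0496), and 2 rose when adjusted over the list alone (median 1.38, camera adjusted p = 0.00322).

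Of 17 visceral endoderm genes all had negative folds in Eng+Flk1+ against Eng-Flk1- and 6 fell (7 when adjusted over the list alone), with a median of -2.90 (camera adjusted p = 1.65e-10). Cubn (-6.85 ± 1.08, limma adjusted p = 0.00953), Apoa4 (-5.14 ± 0.75, 0.00641), Apoc2 (-4.84 ± 0.69, 0.00537) and Ttr (-3.12 ± 0.52, 0.0119) were among them. Of 17 epithelial genes 4 fell (6 when adjusted over the list alone; median -1.65, camera adjusted p = 2.51e-07): Spint2 (-6.87), Prss8 (-4.79), Epcam (-4.17) and Cd24a (-2.75). Of 10 epiblast genes the pluripotency factors Pou5f1 (-3.13), Sox2 (-7.23) and Otx2 (-7.55) fell (5 fell when adjusted over the list alone; median -1.32, camera adjusted p = 0.000127). Of 11 neuroectoderm genes 3 fell over all genes and over the list alone, Zic2 (-3.84), Sox2 and Otx2 (median -0.53, camera adjusted p = 0.000685; adjusted p = 0.0725 with an estimated correlation). Of 9 definitive endoderm genes 1 fell, Cer1, at least 248-fold lower, and 2 fell when adjusted over the list alone (median -0.63, camera adjusted p = 0.00474). Of 17 primitive erythroid genes Hba-a1 (-10.22 ± 1.104) and Hbb-bh1 (-5.26 ± 0.60) fell, and 4 fell when adjusted over the list alone (median -0.77, camera adjusted p = 0.0161; adjusted p = 0.0570 with an estimated correlation).

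In all, 542 genes changed in Eng+Flk1+ against Eng-Flk1-, 449 higher and 93 lower. The largest rises included Anxa5 (6.51), Arap3 (6.36 ± 0.52, limma adjusted p = 0.000317), Grap (6.28), Polg (6.17), Acvrl1 (6.08), Exoc3l2 (5.97) and Fgd5 (5.77). Tspan14 was at least 265-fold, Eogt at least 136-fold, Zfp711 at least 122-fold, Gap43 at least 107-fold and Twist1 at least 13.6-fold higher. Mef2c (5.65), Tbx20 (3.86), Bmp4 (4.89) and the intermediate filament Vim (4.24) also rose. Hba-a2 (-8.07), Myorg (-7.53), the Wnt receptor Fzd3 (-6.45), Mt2 (-6.31), Eraf (-5.81), the lysosomal protease Ctsc (-5.79), Cdx2 (-4.80) and the glucose transporter Slc2a3 (-3.77) fell, and Ccnb3 was at least 3.70-fold lower.

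The groups of Eng+Flk1+ against Eng-Flk1- share no slide, and with the slide as a block limma called 0 genes (1265 at an unadjusted p under 0.05, against 3527). Kdr had a fold of 7.58 ± 2.01 with the block (limma adjusted p = 0.497; 0.000950 to 0.497 over its alternatives). Of the 9 lists called, 6 kept their calls with the block, with medians of 3.17 (endothelial), 1.72 (blood regulators), -2.64 (visceral endoderm), -1.15 (epiblast), -1.50 (epithelial) and -0.69 (primitive erythroid). Mesenchymal genes gained a call with the block (median 0.82, against 0.13 without it). Neuroectoderm (-0.76, 0.0545; 0.000241 to 0.0725 over its alternatives), Notch response (1.00, 0.0545; 0.00134 to 0.0545) and definitive endoderm (-0.49, 0.0503; 0.00281 to 0.554) lost theirs. The count of genes was 1045 without Eng-Flk1- replicate 2, and 303 and 284 without Eng+Flk1+ replicates 1 and 3. The primitive erythroid call was lost without Eng-Flk1- replicate 1 or 2 (0.0587 and 0.0604).

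In the 3 comparisons against Eng-Flk1-, the share of higher genes among those called moved with the scaling. At the 75th percentile the share of higher genes was 84.6% in Eng+Flk1- against Eng-Flk1-, 85.7% in Eng-Flk1+ against Eng-Flk1- and 82.8% in Eng+Flk1+ against Eng-Flk1-. With centring on the median it was 61.5% (144 higher, 90 lower), 54.9% (197 and 162) and 59.4% (225 and 154), and with quantile normalization 68.9% (164 and 74), 52.9% (352 and 313) and 67.6% (305 and 146). With normexp it was 70.4% (107 and 45), 72.2% (190 and 73) and 70.8% (218 and 90). The median log2 fold of all genes was -0.06, -0.13 and -0.06 at the 75th percentile and -0.63, -0.73 and -0.66 with centring on the median, -0.12, -0.19 and -0.11 with quantile normalization, and -0.27, -0.35 and -0.25 with normexp. For the interaction it was 0.13, 0.71, 0.26 and 0.36 in the same order.

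**Figure D3:**
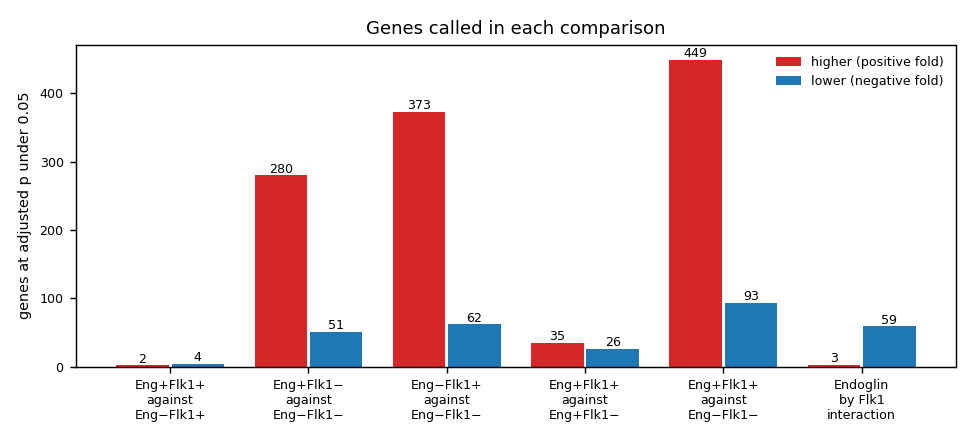
Genes at a limma adjusted p under 0.05 (y axis, count) in each comparison (x axis), higher in red and lower in blue; bars start at 0. The 3 comparisons against Eng-Flk1- hold 331, 435 and 542 genes, the other pair 6 and 61, and the interaction 62. With array quality weights, chosen after seeing the data and not drawn, the counts were 101, 167 and 168, 51 and 214, and 47.

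The interaction asks whether the effect of Endoglin differs between Flk1 positive and Flk1 negative cells; a negative value means a lower Endoglin effect among Flk1 positive cells. A low level in Eng-Flk1- alone also gives a negative value, and a high level there alone a positive one. Genes of allantois and trophoblast had lower Endoglin effects among Flk1 positive than among Flk1 negative cells. Of 14 genes of extraembryonic mesoderm and allantois 2 passed, Foxf1 (-7.54 ± 1.06, limma adjusted p = 0.0230) and Bmp4 (-6.13 ± 0.88, 0.0245), and 7 passed when adjusted over the list alone (median -3.17, camera adjusted p = 2.39e-05). Of 14 trophoblast genes 0 passed over all genes and 6 when adjusted over the list alone, all negative (median -2.06, camera adjusted p = 2.39e-05). Mesenchymal genes had a median of -1.12 (0.00148; 3 of 15 when adjusted over the list alone), and visceral endoderm genes one of 2.13 (0.000154; 5 of 17 when adjusted over the list alone), with 0 of either passing over all genes. The 20 endothelial genes had a median of 1.58 with 3 passing when adjusted over the list alone (0.00111; adjusted p = 0.105 with an estimated correlation), and the 17 epithelial genes one of -1.06 with 1 (0.00911; adjusted p = 0.0532 with an estimated correlation). The 16 cell cycle genes (-0.85, 0.0146; adjusted p = 0.169 with an estimated correlation) and 9 definitive endoderm genes (2.27, 0.0239; adjusted p = 0.0991 with an estimated correlation) had 0 passing either way.

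In all, 62 genes passed the test of the interaction, 3 positive and 59 negative. The 3 positive were Npl (7.40 ± 1.19, limma adjusted p = 0.0375), the vitamin B12 carrier Tcn2 (4.34 ± 0.65, 0.0265) and the adult beta globin Hbb-bt (3.58 ± 0.57, 0.0356). Among genes well above background on all 12 arrays, the largest negative values besides Foxf1 and Bmp4 were those of Cntrob (-7.77), Dad1 (-7.50 ± 0.57, 0.00156), Gprasp1 (-7.25), Ndufv2 (-6.97), Mrpl30 (-6.40) and Mtbp (-5.70). Kdr had a value of -0.30 ± 1.36 (0.955) and Eng of 0.64 ± 0.97 (0.830). With the slide as a block limma called 0 genes for the Endoglin by Flk1 interaction (1412 at an unadjusted p under 0.05, against 2390), and 7 of the 8 lists kept their calls, with medians of -3.11 (allantois), -2.04 (trophoblast), -1.27 (mesenchymal), 0.91 (visceral endoderm), 1.495 (endothelial), -0.83 (epithelial) and -0.74 (cell cycle); definitive endoderm (1.29, 0.143; 0.0116 to 0.251 over its alternatives) lost its call. These block values rest on 1 array of each Flk1 positive fraction, Eng-Flk1+ replicate 1 and Eng+Flk1+ replicate 3. The interaction contains the Eng-Flk1- arrays, and its count moved with them: it was 174, 311 and 132 without replicates 1, 2 and 3 of that fraction, 25 and 28 without Eng-Flk1+ replicates 1 and 3, and 39, 23 and 36 without Eng+Flk1- replicates 1, 2 and 3. Leaving out 1 array ended the call of the epithelial list (Eng-Flk1- replicate 2, 0.102), of the cell cycle list (Eng+Flk1- replicate 3, Eng-Flk1+ replicate 1 and Eng+Flk1+ replicate 2; 0.0583, 0.0667 and 0.114) and of the definitive endoderm list (Eng-Flk1- replicates 1 and 2, Eng+Flk1- replicate 1 and Eng+Flk1+ replicate 1; 0.0540, 0.0609, 0.0544 and 0.0547).

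**Figure D4:**
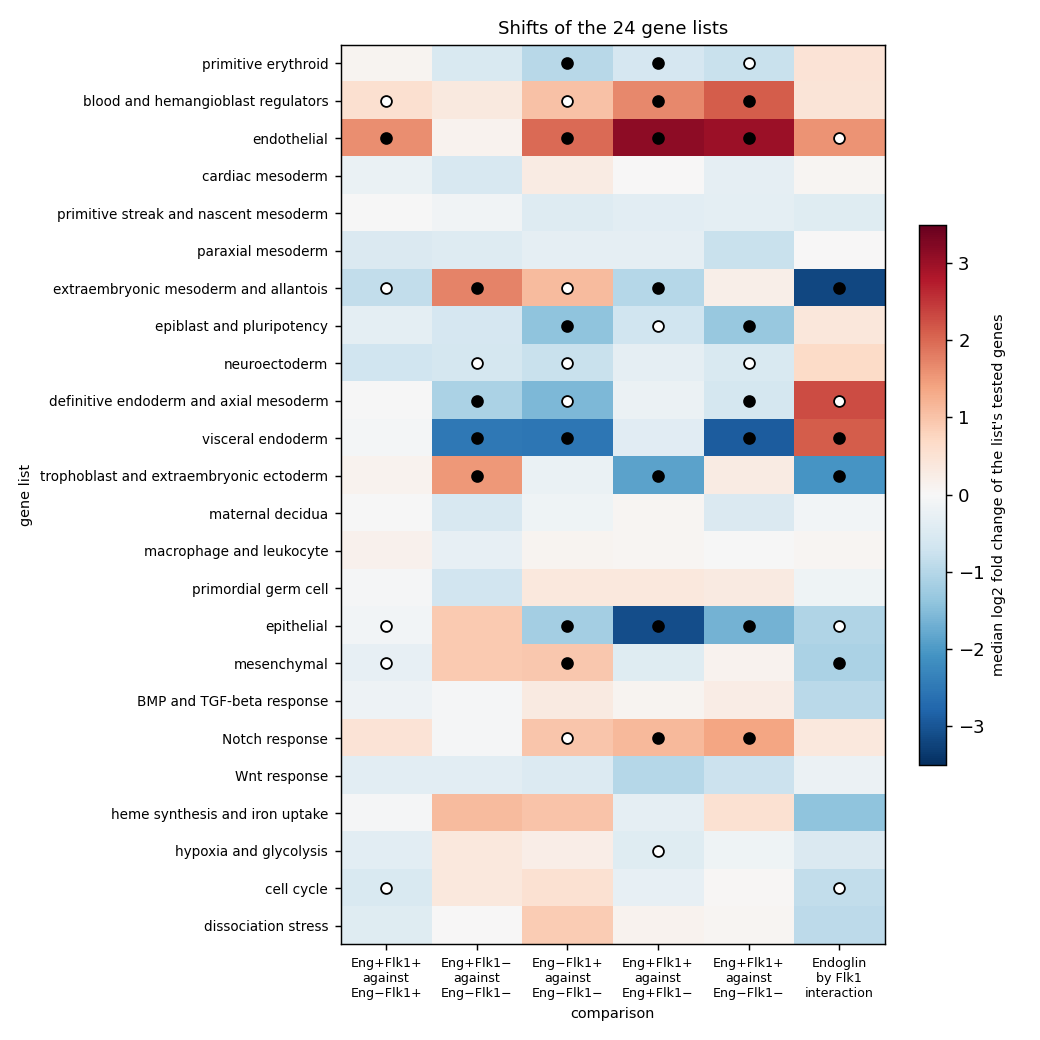
Median log2 fold (colour) of each of the 24 gene lists (y axis) in the 5 comparisons and the interaction (x axis); black dots mark lists called by camera with both the preset and the estimated correlation, and white dots those called with the preset alone. The endothelial list reaches 3.13 and the epithelial list -3.11 in Eng+Flk1+ against Eng+Flk1-.

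A further 10 lists were not called in any comparison. Their lowest camera adjusted p was 0.0603 for cardiac mesoderm, 0.0865 for primitive streak and nascent mesoderm, 0.112 for paraxial mesoderm, 0.107 for primordial germ cell, 0.0912 for BMP and TGF-beta response, 0.141 for Wnt response and 0.118 for heme synthesis and iron uptake. It was 0.5005 for maternal decidua, 0.523 for macrophage and leukocyte, and 0.310 for dissociation stress.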

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

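The splits of the arrays were planned before the result was seen; the tests of slide 3, of extraembryonic ectoderm cells, of primitive red cells and of maternal blood were chosen only after it was seen, and what would decide these 4 was changed once their values were known.

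The Endoglin effect, a difference between sorted fractions with and without the protein, differed between Flk1 positive and negative cells for 62 genes, 59 negative. This is by the test of the interaction itself, which contains the Eng-Flk1- arrays and gave 174, 311 and 132 genes without each of them. The log2 difference between the Endoglin effects was 7.40 for Npl, 4.34 for Tcn2, 3.58 for Hbb-bt, -7.77 for Cntrob, -7.54 for Foxf1, -7.50 for Dad1, -7.25 for Gprasp1, -6.97 for Ndufv2, -6.40 for Mrpl30, -6.13 for Bmp4 and -5.70 for Mtbp. A gene low in Eng-Flk1- alone also gives a negative value, and a gene high there alone a positive one. Among Flk1 positive cells the Endoglin effect was 0.07 ± 0.62 for Bmp4 and -2.50 ± 0.75 for Foxf1. The value of Bmp4 thus rests on its low level in Eng-Flk1-. Dad1, Ndufv2 and Mrpl30 were among the largest rises in Eng+Flk1- against Eng-Flk1-. For such genes a low signal in Eng-Flk1- and a differing effect of Endoglin cannot be told apart. Hbb-bt had a level of 5.67 in Eng-Flk1-, against 2.10 in Eng+Flk1-, 1.61 in Eng-Flk1+ and 1.62 in Eng+Flk1+. Its positive value thus rests on its high level in Eng-Flk1-. The visceral endoderm list had a median of -2.50 in Eng+Flk1- against Eng-Flk1-, but of -0.07 in Eng+Flk1+ against Eng-Flk1+. By camera, 8 lists also differed: endothelial (adjusted p = 0.00111), extraembryonic mesoderm and allantois (2.39e-05), definitive endoderm and axial mesoderm (0.0239), visceral endoderm (0.000154), trophoblast and extraembryonic ectoderm (2.39e-05), epithelial (0.00911), mesenchymal (0.00148) and cell cycle (0.0146). With an estimated correlation 4 of the 8 held, while endothelial (adjusted p = 0.105), epithelial (0.0532), cell cycle (0.169) and definitive endoderm (0.0991) lost their calls. Of 100 drawn splits of the 12 arrays into 4 groups of 3, only the real one, counted as 1, called as many genes (62, against 34 at most in the others), so a random grouping of all 12 is excluded at that number of splits; this does not test the interaction apart from the differences between fractions, which the other splits mix into the spread, nor apart from the slide, with which limma called 0 genes (1412 at an unadjusted p under 0.05). The slide block estimate of the interaction rests on 1 array of each Flk1 positive fraction, Eng-Flk1+ replicate 1 and Eng+Flk1+ replicate 3. With the slide as a block the allantois, trophoblast and mesenchymal lists had medians of -3.11, -2.04 and -1.27, against -3.17, -2.06 and -1.12 without it. The visceral endoderm list moved from 2.13 to 0.91, and definitive endoderm lost its call.

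Trophoblast genes were higher in Eng+Flk1- than in Eng-Flk1- and in Eng+Flk1+. Slide 3, which holds all Eng+Flk1- arrays, and the fraction cannot be told apart: with the slide as a block the list had a median of -1.93 in Eng+Flk1+ against Eng+Flk1-, but this rests on the 1 Eng+Flk1+ array on slide 3. Extraembryonic ectoderm cells within the Eng+Flk1- fraction stay open: 5 of the 14 members (Elf5, Eomes, Esrrb, Hand1 and Rhox9) had all 3 of its arrays above the other 9, against 0.801% of all genes tested, which follows from the list being high there. The epithelial list was lower in Eng+Flk1+ than in Eng+Flk1- (median -3.11, camera adjusted p = 9.77e-18) and 3 of its 17 members had the same ranking, but it was not called in Eng+Flk1- against Eng-Flk1- (median 0.92, 0.238). Hand1 is also a gene of cardiac and extraembryonic mesoderm and Eomes one of the primitive streak, and 3 of 14 allantois genes had the same ranking, so expression of these genes in Endoglin positive mesoderm remains open and was not tested.

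Adult globin transcripts were high in Eng-Flk1-, where Hba-a1 had a level of 8.38 ± 0.48, Hba-a2 of 7.40 ± 0.46 and Hbb-bt of 5.67 ± 0.33 (SD, n = 3). Primitive red cells as the only source stay open: the embryonic globins Hbb-bh1, Hba-x and Hbb-y were higher than in Eng+Flk1- by a median of 1.17 (adult globins Hba-a1, Hba-a2 and Hbb-bt 6.48), but higher than in Eng-Flk1+ by 5.08 (7.68) and than in Eng+Flk1+ by 5.26 (8.07). Blood of the mother, which carries neither marker on its red cells, may be a source, as the adult median exceeded the embryonic median by 5.31, 2.59 and 2.80 in these differences. The adult median against Eng+Flk1- was the value of Hba-a2, an alpha globin. Hbb-bt, the only beta globin among the adult genes, was higher than in Eng+Flk1- by 3.57 ± 0.40. Its levels in Eng-Flk1+ and Eng+Flk1+ were 1.61 and 1.62, so it differed there by less than the embryonic medians. Against these 2 fractions the adult excess thus rests on the alpha globins. The macrophage and leukocyte list was not called in any comparison (lowest camera adjusted p 0.523), Hba-a1 also belongs to the primitive erythroid list, and the near identity of Hba-a1 and Hba-a2 means that their probes are not independent. A difference in the share of the embryo's own red cells between the fractions remains open, together with a source in the mother.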

How the results depend on the processing

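The array quality weights and the fits without the 3 Eng-Flk1- arrays were chosen only after the result was seen; the other alternatives were planned. Counts are given in the order Eng+Flk1+ against Eng-Flk1+ (6), Eng+Flk1- against Eng-Flk1- (331), Eng-Flk1+ against Eng-Flk1- (435), Eng+Flk1+ against Eng+Flk1- (61), Eng+Flk1+ against Eng-Flk1- (542) and the Endoglin by Flk1 interaction (62). With normexp background correction they were 3, 152, 263, 98, 308 and 40. Quantile normalization gave 7, 238, 665, 95, 451 and 39, and centring on the median 4, 234, 359, 52, 379 and 32, as did the authors' table. Without the filter on dim probes they were 3, 257, 361, 42, 431 and 45. Asking for signal well above background on all 12 arrays, which tests 17447 genes, gave 0 (730 at an unadjusted p under 0.05), 166, 198, 37, 257 and 21. An intensity trend gave 0 (1049), 335, 438, 71, 543 and 58. Every probe tested on its own gave 11, 635, 822, 103, 925 and 176 genes with at least 1 probe called. An adjusted p under 0.01, a stricter threshold by construction, left 0, 90, 124, 16, 169 and 18. A minimum of 2-fold left all 6 counts as they were. It could remove no gene, as the smallest fold of a called gene was 3.34, in Eng+Flk1+ against Eng-Flk1-. The compared arrays alone gave 9, 186, 305, 100 and 263, with no value for the interaction. Array quality weights gave 51, 101, 167, 214, 168 and 47. Without the 3 Eng-Flk1- arrays the first comparison gave 13 and Eng+Flk1+ against Eng+Flk1- 129. Among called genes, normexp reversed the sign of 4 of 331, 10 of 435 and 7 of 542 in the comparisons against Eng-Flk1-, and the slide as a block that of 1 of 331. Apart from the thresholds and the filter, the cause was not tested.

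With the slide as a block limma called 0 (774 at an unadjusted p under 0.05), 0 (1007), 16, 12, 0 (1265) and 0 (1412) genes; within slides that hold both groups, in the 3 comparisons that have one, it called 0 (774), 16 and 12. With the replicate number as a block it called 0 (1043), 237, 309, 23, 401 and 23. The numbers do not pair the samples: of 18 pairs of arrays with the same number, 1 had a correlation of residuals above 0.1, with a range of -0.0898 to 0.130.

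Leaving out 1 array in turn gave 3 to 22, 149 to 851, 164 to 1011, 28 to 106, 284 to 1045 and 23 to 311 genes. The lowest counts were without Eng+Flk1- replicate 3, Eng+Flk1- replicate 3, Eng-Flk1+ replicate 3, Eng+Flk1- replicate 3, Eng+Flk1+ replicate 3 and Eng+Flk1- replicate 2. The highest were without Eng+Flk1+ replicate 3, Eng-Flk1- replicate 2 (in the 3 comparisons against Eng-Flk1- and the interaction) and, for Eng+Flk1+ against Eng+Flk1-, Eng-Flk1- replicate 3. In all 12 of these fits 1 of 6, 102 of 331, 127 of 435, 16 of 61, 197 of 542 and 18 of 62 genes passed, and 0 changed sign. Of 3456 values under leave-outs, from 288 results on named genes (a gene counts once per comparison in which it is named), 3015 kept direction and side of the threshold, 397 lost their call, 39 gained one and 5 without a call changed sign. With the slide as a block 135 of the 288 kept both, 150 lost their call and 3 that had none changed sign. Results that kept both include those called in neither fit, here and under the leave-outs. Of all called genes, 0 of 6, 0 of 331, 16 of 435, 7 of 61, 0 of 542 and 0 of 62 stayed called with the slide as a block. Of the 144 tests of lists, 125 kept their side with an estimated correlation, which includes lists called in neither, and 19 lost the call. Of the called lists, in the same order of comparisons, 1 of 6, 4 of 5, 6 of 11, 7 of 9, 7 of 9 and 4 of 8 held. Signal over background limits the folds of 4 of the 6, 70 of the 331, 104 of the 435, 13 of the 61 and 121 of the 542 genes to lower bounds, as they were well above background on no array of the lower group.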

Other observations

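The tests of random loss and the splits of the arrays were planned before the result was seen; the tests of slide 1 and of the scaling were chosen only after it was seen, and what would decide the tests of genes missing on all 3 arrays and of the scaling was changed after it was seen.

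Some globins, chosen after their values were seen, are given by fraction; each was tested between fractions, but no globin was tested against another. The embryonic globin Hbb-bh1 had levels of 3.82 ± 1.17 (SD, n = 3) in Eng-Flk1- and 2.66 ± 0.38 in Eng+Flk1-, against -1.26 in Eng-Flk1+ and -1.44 in Eng+Flk1+. The adult beta globin Hbb-bt had levels of 5.67 ± 0.33 in Eng-Flk1- and 2.10 ± 0.17 in Eng+Flk1-, against 1.61 and 1.62 in the Flk1 positive fractions. In Eng-Flk1- minus Eng+Flk1-, Hbb-bt differed by 3.57 ± 0.40 (limma adjusted p = 0.00279), Hbb-bh1 by 1.17 ± 0.60 (0.415), Hba-x by 2.30 ± 1.73 (0.573) and Hbb-y by 0.81 ± 0.83 (0.691).

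The Eng-Flk1- arrays stood apart from the other 9, and most genes that changed against them were lower in Eng-Flk1-. Random loss of transcripts in single amplifications stays open for genes missing on all 3 Eng-Flk1- arrays and present on the other 9: they were 30.8 times as many as the 3.41 expected if each array lost genes of a given brightness on its own, but the same ratio was 87.1 in Eng-Flk1+ (2 genes, 0.0230 expected), 585 in Eng+Flk1+ (3 genes, 0.00513 expected) and 0 in Eng+Flk1- (0 genes), and the bound set beforehand assumed equal loss within a brightness, which was not tested. It stays open for the spread among these arrays, with 9.80% of 19459 genes missing on 1 or 2 of the 3, against at most 1.21% in another fraction. The part of the scaling in the direction stays open: over 3 other scalings the lowest share of higher genes was 52.9% in Eng-Flk1+ against Eng-Flk1- (from 85.7%), 59.4% in Eng+Flk1+ against Eng-Flk1- (from 82.8%) and 61.5% in Eng+Flk1- against Eng-Flk1- (from 84.6%), but in the first, by quantile normalization, 352 genes were called higher (against 373) and 313 lower (against 62), and the other 2 come from centring on the median, which shifts all genes of an array alike (quantile normalization gave 67.6% and 68.9%, normexp 70.8% and 70.4%). Slide 1 and the fraction cannot be told apart, as only 1 array of another fraction lies on it, Eng-Flk1+ replicate 1. Over the 449 genes called lower in Eng-Flk1- than in Eng+Flk1+, that array was shifted by a median of -0.129 below its 2 fellow arrays (that is, it lay above them). The median gap between Eng+Flk1+ and Eng-Flk1- over these genes was 4.43. With 1 such array this alone excludes nothing. A difference in the cells themselves also stays open and was not tested.

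Splitting the 6 arrays of a comparison into 3 and 3 in other ways gives 10 splits, too few for a share under 0.05. The real split, counted as 1, called 6 genes in Eng+Flk1+ against Eng-Flk1+, where the highest other split called 2. The real and highest other counts were 331 and 4 in Eng+Flk1- against Eng-Flk1-, 435 and 3 in Eng-Flk1+ against Eng-Flk1-, 61 and 1 in Eng+Flk1+ against Eng+Flk1-, and 542 and 13 in Eng+Flk1+ against Eng-Flk1-. Every other split mixes arrays of both fractions, which adds the difference between them to the spread. The counts of the other splits are thus not a level that chance alone would give.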
